A study of Mus musculus with 8 samples.

How the data were processed

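Microglia were isolated from the cortex of 8 mice at postnatal day 30, 4 h after a unilateral injection of IL-33 or vehicle into a cerebral ventricle. Per the labels' protocols, tissue was homogenized in the cold, cells were enriched on a 22% Percoll gradient and collected by fluorescence-activated sorting, and libraries were made with the Nugen Ovation RNA-Seq System V2. The markers used for the sorting gate are not given in the sources used here. The labels put 4 mice in the IL-33 group (mice 1 to 4) and 4 in the vehicle group (mice 5 to 8), with 2 females and 2 males in each. The header of the deposited table names the vehicle columns PBS.

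The deposited expression values are a signal in normalized counts per gene and mouse, made by the authors by dividing read counts by 1 size factor per library. The submitters' processing notes name FastQC, STAR 2.6.0, HTSeq 0.9.0 and DESeq2 1.24.0 and the builds mm10 and GRCm38, without a role or an order. The strand setting, the annotation release and the filters are not given in the sources used here. Antisense and overlapping genes are therefore uncertain, as are genes that share reads with near-identical copies, such as ribosomal protein genes with their processed pseudogenes. In each library 100% of values were whole multiples of the smallest step, within a tolerance of 0.001 reads, so whole reads could be recovered. The authors also deposited a table of their own comparison. Per the file headers, the table deposited by the authors holds mean normalized counts, log2 fold changes of IL-33 over vehicle with standard errors on the log2 scale, a score (the log2 fold change divided by its standard error), and p-values with adjusted p-values. The table deposited by the authors lists 7029 genes, and its highest adjusted p is 0.00996.

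Genes were identified by their Ensembl identifiers, of which 53706 of 53801 were found in GENCODE M21 (GRCm38), and names and coordinates were taken from there. The symbols deposited beside the identifiers in the normalized counts were not used. They matched GENCODE for 49609 identifiers and differed for 4097, and 261 identifiers carried the symbol of another gene, 209 of them on chromosome 8. All 8 columns were matched to their mice by name, and 0 columns of per-sample values were left unmapped. Over 12 pairs of mice of one group, the chi-square of recovered reads per gene lay between 4.26 and 21.2, so that all pairs differed beyond sampling noise and each mouse was counted as 1 replicate.

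Recovered depth ran from 6989640 reads (vehicle mouse 6) to 9323677 reads (vehicle mouse 5). Intervals and floors from read counts (95%, exact Poisson, with 3 counts behind a floor) cover counting error only, since reads without molecular identifiers are not independent molecules. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust) on log2 of the normalized count plus a pseudocount of 1, with terms for treatment and sex. Fold changes are differences of mean log2 values on that scale: the pseudocount draws those of low genes towards 0, while uneven mice within a group can make them larger or smaller than the ratio of the group means. Genes with a normalized count of 10 or more in at least 4 of the 8 libraries were tested, and a Benjamini-Hochberg adjusted p under 0.05 was called. The sex comparison took the sex term of the same model, and the difference of the IL-33 effect between the sexes took an interaction term with 2 mice per treatment and sex. All tests were two-sided. Where a gene is said to have risen or fallen, the adjusted p is from this test.

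Gene lists (36 lists with 982 entries, 10 of them markers of other cell types and 1 of sex chromosome genes) were fixed from textbook knowledge. Camera tested 32 lists with at least 5 tested members, with a preset correlation of 0.01 between genes, and was repeated with an estimated correlation and with fry. Fry tests whether the members of a list move, on balance, one way, and does not compare them with other genes. A dendritic cell list was added after the values were seen.

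The genes named are a fixed panel of 17, the 6 largest rises and the 6 largest falls among called genes with a mean normalized count of 50 or more and no overlap between the groups, up to 4 called members of each list with the largest change (or, with none called, the member with the highest mean), and up to 6 genes with the smallest adjusted p for the sex comparison and for the interaction. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Some genes that met the rule are not reported here. Genes named outside this rule were chosen after their values were seen and are marked so.

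The limma test was tested on simulated data with 14520 genes for IL-33 against vehicle. It recovered 36.1%, 73.8% and 96.8% of genes changed by 0.5, 1 and 2 on the log2 scale, with 7 false calls among 14336 unchanged genes. With so few genes changed, the adjusted p asks for a smaller unadjusted p than in the real comparison, where 57.7% of genes were called. The shares recovered for IL-33 in the real data may therefore be higher and were not measured. For the sex comparison (14525 genes) it recovered 43.8%, 71.4% and 100% of such genes. For the interaction (14516 genes) the shares were 1.56%, 33.3% and 59.7%.

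Alternatives were pseudocounts of 0.5 and 5, no filter on low values, a filter of 50, TMM factors, quantile normalization, array weights, eBayes without trend and not robust, no sex term, each sex alone, an adjusted p under 0.01, a log2 fold change of at least 1 in size, and each mouse left out in turn. The edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0 were run on the recovered reads and called 8683 and 8392 genes, against 8716 by limma. The list counts without vehicle mouse 6, list tests on the interaction, and list tests with array weights, without trend and within each sex were added after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and robust fits used statmod 1.5.0.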

Results

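RNA from sorted cortical microglia was sequenced for 8 mice, 4 injected with IL-33 and 4 with vehicle, with 2 females and 2 males per group. IL-33 is a cytokine of the interleukin-1 family that signals through the receptor encoded by Il1rl1. Total recovered reads per mouse lay between 6989640 and 9323677. Ribosomal RNA, of nuclear and mitochondrial genes together, took 9.0% to 10.4% of reads, and mitochondrial messenger RNA took 0.572% to 0.711%. Values below are normalized counts as mean ± SD with n = 4 mice per group unless stated, and adjusted p-values are limma's unless another test is named. Coordinates are GRCm38 with GENCODE M21 annotation. For each gene named with a value as risen or fallen with IL-33, all 4 IL-33 mice lay beyond all 4 vehicle mice, except where stated. Counts of genes that rose or fell, for lists and for all genes, rest on the limma call alone, and the groups can overlap in such genes.

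The first comparison asked which genes differed in microglia 4 h after IL-33. Scavenger receptor, interleukin and chemokine genes that were nearly unread in vehicle mice reached high normalized counts. Marco, a scavenger receptor that binds bacteria (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), rose from 1.68 ± 1.14 to 4366 ± 627, a log2 fold change of 10.81 ± 0.29 (SE, adjusted p = 7.54e-12). Il12b, a subunit of interleukin-12 and interleukin-23 (chromosome 11, 44400063 to 44414033), rose from 8.72 ± 9.71 to 10851 ± 3602 (log2 10.62, adjusted p = 4.69e-05). Over the same 4 h, P2ry12, a purinergic receptor that marks resting microglia (chromosome 3, 59216272 to 59262871), fell from 28549 ± 2744 to 3974 ± 411 (log2 -2.85, adjusted p = 5.74e-14).

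Of 15110 genes tested, 8716 (57.7%) were called, 4407 higher and 4309 lower with IL-33. Of the called genes, 1694 were at least 1 log2 unit higher and 2167 at least 1 log2 unit lower. A rise of 6 or more log2 units was seen for 57 called genes, and a fall of -4 or beyond for 20. Over all tested genes, the values of the groups did not overlap in 7905 (52.3%), where chance gives 2.86%, and 7587 of these were called. The direction was the same in females and males for 8710 of the called genes. The call averages over both sexes of the same mice, which favours such agreement, so this count is no separate evidence. The median log2 fold change of all tested genes was 0.02. Size factors set the centre of the changes near 0, so this median and the near-even split of directions follow in part from the scaling. TMM factors and quantile normalization centre the values in a similar way, so a change in total RNA per cell could not be seen. In females alone, with 2 mice per group, 10 of the named genes lost the call, among them Il1rn, Cxcl10, Ch25h, Lpl and Cdkn1a, and in males alone 5 did, among them Rsad2, 5730435O14Rik, H2-Aa and H2-Ab1.

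The 6 largest rises by the naming rule were Marco, Il12b, Ccr7, Ccl22, Cd40 and Itgal. Ccr7, a chemokine receptor that guides cells to lymph nodes, rose from 3.04 ± 3.93 to 3021 ± 557 (log2 10.03), and Ccl22, a chemokine that attracts T cells (chromosome 8, 94745590 to 94751699), from 10.5 ± 3.37 to 9319 ± 1222 (log2 9.71, adjusted p = 1.46e-12). Cd40, a costimulatory receptor, rose from 0.881 ± 1.19 to 599 ± 69.3, and Itgal, an integrin subunit of leukocytes, from 11.8 ± 5.97 to 4304 ± 441. The 6 largest falls were 5730435O14Rik, Adamts16, Cbfa2t3, Gm28512, Gm24225 and Mycl, with log2 fold changes of -5.01, -4.87, -4.37, -4.21, -4.19 and -4.06. Adamts16 encodes a secreted metalloproteinase and fell from 352 ± 89.2 to 10.8 ± 1.32. Cbfa2t3, a transcriptional corepressor, fell from 499 ± 133 to 24.5 ± 10.7, and Mycl, a MYC family transcription factor, from 184 ± 50.7 to 10.2 ± 3.69. Gm28512 is annotated as sense intronic, so reads of its host gene cannot be excluded from its count. Single mice moved some of these falls by more than 1.5-fold: 5730435O14Rik was at -5.96 without IL-33 mouse 3 and -4.18 without IL-33 mouse 4, and Gm28512 was at -3.42 without IL-33 mouse 4.

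**Figure D1:**
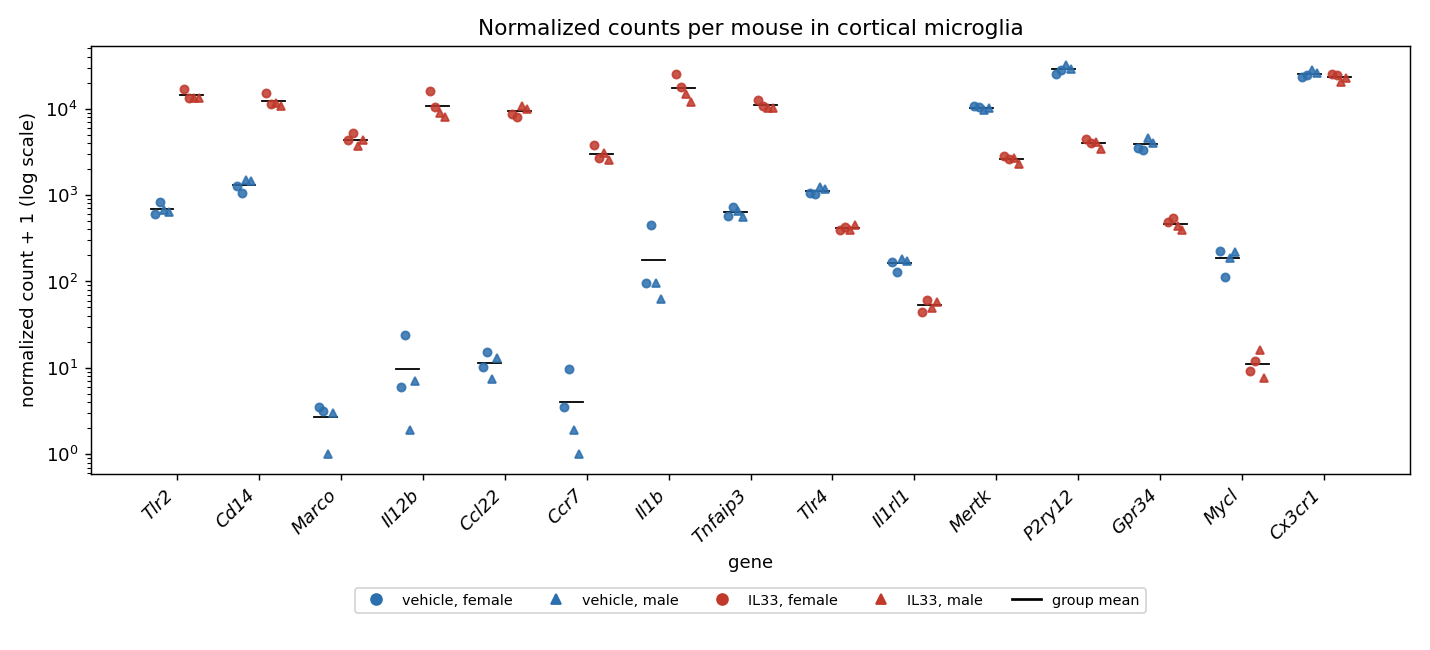
Normalized count plus 1 (log axis) of 15 genes in each of the 8 mice, with vehicle in blue, IL-33 in red, circles for females, triangles for males and black bars for group means. Marco lay at 0 to 2.52 in vehicle mice and at 3663 to 5189 in IL-33 mice, while Cx3cr1 was not called.

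The receptor for IL-33 and its partner moved apart. Il1rl1, the IL-33 receptor (chromosome 1, 40429570 to 40465415), fell from 162 ± 23.8 to 52.2 ± 7.77 (log2 -1.62 ± 0.18 SE, adjusted p = 5.39e-07). Il1rap, its co-receptor, rose from 65.8 ± 8.96 to 196 ± 21.9 (log2 1.56). Irak3, a kinase-like protein that restrains signalling from this receptor family, rose by a log2 fold change of 3.82, and Irak2, a kinase of the same pathway, by 1.28. Among 16 tested genes of IL-33 receptor and adaptor signalling, 9 rose, 4 fell and 3 were not called, and adjusted over the list alone 9 rose and 5 fell (camera adjusted p = 0.168). Il33 itself was below the filter, with 6 reads of 31993955 in the IL-33 group and 7 of 32806198 in the vehicle group. These are 0.188 RPM (exact Poisson 95% interval 0.0688 to 0.408) and 0.213 (0.0858 to 0.440), so a difference was not detectable at this depth.

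Targets and inhibitors of the transcription factor NF-kB rose almost throughout. Of 34 tested, 33 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 3.20 (camera adjusted p = 8.80e-20, and adjusted p = 0.143 with an estimated correlation). Nfkbia, which holds NF-kB in the cytoplasm, rose by 3.35 log2 units (adjusted p = 0.000178), and Tnfaip3, a ubiquitin-editing enzyme that ends NF-kB signalling, rose from 629 ± 77.9 to 10975 ± 1067 (log2 4.13). Gadd45b, a stress-response gene, rose by 7.16, and Tnfaip2 by 7.10. The member that fell was Plau, the urokinase gene, at -1.78, named after its value was seen. Of 24 tested genes of negative feedback on cytokine signalling, 20 rose, 2 fell and 2 were not called, with the same counts adjusted over the list alone (median 2.74, camera adjusted p = 4.45e-08, and adjusted p = 0.143 with an estimated correlation). Dusp2 and Dusp1, phosphatases that switch off MAP kinases, rose by 6.80 and 6.09. The NF-kB, feedback, immediate-early and glucocorticoid lists share members, Nfkbia and Dusp1 among them.

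Cytokine and chemokine genes held many of the largest rises. Of 20 tested cytokines 12 rose, 4 fell and 4 were not called, and 13 rose and 4 fell adjusted over the list alone (median log2 1.39, camera adjusted p = 0.000587, and adjusted p = 0.143 with an estimated correlation). Il1b rose from 175 ± 183 to 17431 ± 5655 (log2 7.04, adjusted p = 0.000134) and Tnf from 125 ± 84.8 to 7521 ± 1925 (log2 6.11, adjusted p = 1.45e-05). Il1rn, the natural antagonist of the interleukin-1 receptor, rose by 6.54, and Tnfsf9, a ligand that costimulates T cells, by 6.36. Il1a, chosen after its values were seen, rose by 3.57. Of 19 tested chemokines 17 rose and 2 fell, also adjusted over the list alone (median 4.96, camera adjusted p = 3.01e-10, and adjusted p = 0.143 with an estimated correlation). Cxcl2, which attracts neutrophils, rose by 8.05, Cxcl10, an interferon-inducible chemokine, by 7.34, and Ccl5 by 7.27. Ccl24, an eotaxin, fell by 2.50 on the log2 scale.

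Vehicle mouse 6 lay above the other vehicle mice in several of these genes. Its Il1b was 449, against 62.1 to 95.2 in the other 3, its Cxcl10 was 161 against 12 to 25.2, and its Il1rn was 142 against 4.21 to 40.0. Without this mouse 8712 genes were called, 8225 of them among the 8716, all with the same direction. The log2 fold change of Il1rn was then 7.53, that of Cxcl2 8.68 and that of Cxcl10 8.02, and Il1rn was at 5.61 without vehicle mouse 5. The counts for cytokines (12 up, 4 down) and chemokines (17 up, 2 down) were the same without mouse 6. The ribosomal RNA gene CT010467.1, named after its values were seen, was 26319 in this mouse against 149005 to 159207 in the other vehicle mice. The share of ribosomal RNA, of nuclear and mitochondrial genes together, was 9.0% in it and 9.43% to 9.73% in the others. That total takes in other ribosomal RNA genes and does not show the level of CT010467.1. The log2 fold change of CT010467.1 was 0.02 (adjusted p = 0.987) over all mice and -0.66 (adjusted p = 4.28e-08) without mouse 6.

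Pattern recognition receptors, which bind microbial and damage-derived molecules, went both ways. Of 38 tested, 19 rose, 13 fell and 6 were not called, and 19 rose and 14 fell adjusted over the list alone (median log2 0.31, camera adjusted p = 0.0976). Tlr2, a receptor for bacterial lipoproteins (chromosome 3, 83836272 to 83841767), rose from 689 ± 99.8 to 14289 ± 1671 (log2 4.38 ± 0.09 SE, adjusted p = 2.02e-15), and Cd14, a co-receptor of Toll-like receptors, from 1306 ± 199 to 12242 ± 1973 (log2 3.23). Tlr4, the receptor for endotoxin (chromosome 4, 66827584 to 66930284), fell from 1123 ± 87.7 to 414 ± 26.9 (log2 -1.44, adjusted p = 2.34e-10). Of 10 Toll-like receptors called, 4 were higher and 6 lower. Those beside Tlr2 and Tlr4 were named after their values were seen: Tlr1, Tlr6 and Tlr9 rose by 3.30, 1.27 and 1.21, while Tlr7, Tlr3, Tlr12, Tlr5 and Tlr13 were at -1.93, -1.25, -1.17, -0.51 and -0.30. For Tlr13, 3 of 4 IL-33 mice lay below all vehicle mice, and its call was lost in females alone (-0.09, adjusted p = 0.57) and by eBayes without trend (adjusted p = 0.0714). Clec4a1, a C-type lectin, rose by 4.00, and Msr1, a scavenger receptor, by 3.35. Fpr1, a receptor for bacterial formyl peptides, rose to 46.2 ± 17.6, with 1 read in all vehicle mice together.

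Genes of phagocytosis were likewise divided. Mertk, a receptor for dying cells and debris (chromosome 2, 128698956 to 128802894), fell from 10270 ± 426 to 2615 ± 230 (log2 -1.98 ± 0.07 SE, adjusted p = 3.43e-13), while Axl, a receptor of the same family, rose from 102 ± 26.5 to 675 ± 79.2 (log2 2.75). Of 38 tested genes of phagocytosis and opsonin receptors 13 rose, 16 fell and 9 were not called, and 13 rose and 17 fell adjusted over the list alone. The median log2 fold change was -0.23 and the mean 0.33, and camera's direction was down (adjusted p = 0.407). Vav3, a guanine nucleotide exchange factor, rose by 5.83. Gas6, the ligand of both receptors, and Trem2, a lipid-sensing receptor, both chosen after their values were seen, were at -2.75 and -1.50. Among 16 complement components and receptors 5 rose, 5 fell and 6 were not called, also adjusted over the list alone (camera adjusted p = 0.568). C3, the central complement component, rose by 6.21 from 9.06 ± 5.76, and the receptors C3ar1 and C5ar1 rose by 3.10 and 2.53.

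Genes that mark homeostatic microglia fell as a group, with some exceptions. Of 42 tested, 35 fell, 4 rose and 3 were not called, also adjusted over the list alone (median log2 -1.07, camera adjusted p = 2.52e-12, and adjusted p = 0.147 with an estimated correlation). Gpr34, a lysophospholipid receptor, and Slc2a5, a fructose transporter, were at -3.05 and -2.87. Tmem119, a microglial membrane protein, fell less, from 16373 ± 806 to 10343 ± 925 (log2 -0.67, adjusted p = 5.57e-08). Cx3cr1, the fractalkine receptor, was 25486 ± 2023 with vehicle and 23306 ± 2090 with IL-33 (log2 -0.13 ± 0.08 SE, adjusted p = 0.154) and was not called. In males alone it was called (log2 -0.32, adjusted p = 0.000875) and in females alone it was at 0.057, but the difference between the sexes was not called (adjusted p = 0.341). Gpr84, a receptor for medium-chain fatty acids that stands on this list, rose by 4.56. Of 18 tested genes of TGF-beta signalling, which maintains this state, 10 fell, 6 rose and 2 were not called, and 10 fell and 7 rose adjusted over the list alone (median -0.47, camera adjusted p = 0.224). Pmepa1, a TGF-beta target that limits the pathway, was at -2.73, Smad6, an inhibitory SMAD, at -3.27 (-3.86 without IL-33 mouse 3), and Skil, a repressor of SMAD activity, rose by 1.25. Smad6 rested on 5 reads in the IL-33 group, all in mouse 3, and 60 in the vehicle group, so the size of its fall is uncertain.

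Disease-associated microglia genes and lysosomal genes gave a mixed and a falling picture. Of 34 tested disease-associated genes 14 rose, 12 fell and 8 were not called, and 15 rose and 13 fell adjusted over the list alone (median log2 0.12, mean 0.98, camera adjusted p = 0.305). Ch25h, an enzyme that makes 25-hydroxycholesterol, rose by 8.16 (7.23 without vehicle mouse 5 and 9.06 without vehicle mouse 6), Cybb, a subunit of the NADPH oxidase, rose from 18.3 ± 7.83 to 2342 ± 333, and the chemokines Ccl3 and Ccl4 rose by 6.08 and 5.67. Of 39 lysosome and cathepsin genes 26 fell, 7 rose and 6 were not called, also adjusted over the list alone (median -0.52, camera adjusted p = 0.00047, and adjusted p = 0.51 with an estimated correlation). Ctsd, cathepsin D, fell from 15051 ± 1169 to 5491 ± 680. Ctsc, cathepsin C, rose by 1.43.

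Genes for presenting antigen and for making lipid and oxidative mediators rose in part. Of 27 genes of antigen presentation and costimulation 17 rose, 5 fell and 5 were not called, also adjusted over the list alone (median log2 1.34, camera adjusted p = 7.58e-05, and adjusted p = 0.143 with an estimated correlation). Cd74, the invariant chain of class II molecules, rose from 95.8 ± 17.8 to 2784 ± 353, and Cd83, a maturation marker, by 4.44. The class II genes H2-Aa and H2-Ab1, chosen after their values were seen, stayed low, at 22.9 ± 12.9 and 59.9 ± 16.6 with IL-33 against 3.03 ± 3.21 and 34.0 ± 9.09. The log2 fold change of H2-Aa was 2.82, and 2.12 without vehicle mouse 6 and 3.46 without vehicle mouse 8. Among 28 prostaglandin, nitric oxide and oxidative enzymes 14 rose, 10 fell and 4 were not called, also adjusted over the list alone (median 0.70, camera adjusted p = 0.119). Ptges, a prostaglandin E synthase, rose to 301 ± 69.3, with 1 read in all vehicle mice together, and Acod1, which makes itaconate, to 315 ± 123, with 3 reads. Of 16 alternative activation genes 9 rose, 4 fell and 3 were not called, and 9 rose and 5 fell adjusted over the list alone (median 0.63, camera adjusted p = 0.163). Ccl17, a T-cell chemokine, rose by 4.99 and Cish, a cytokine-inducible inhibitor of STAT signalling, by 3.44.

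Interferon-stimulated genes, the antiviral programme, rose for the most part. Of 47 tested, 31 rose, 3 fell and 13 were not called, and 34 rose and 3 fell adjusted over the list alone (median log2 1.08, camera adjusted p = 1.51e-05, and adjusted p = 0.472 with an estimated correlation). Gbp2 and Gbp5, guanylate-binding proteins, rose by 4.98 and 4.13, and Ifit1 by 2.96. Rsad2, which encodes viperin, rose by 3.30 (adjusted p = 0.0208). Its call was lost without IL-33 mouse 3 (adjusted p = 0.0563), IL-33 mouse 4 (0.0565) or vehicle mouse 5 (0.0693), and it was lost with no filter on low values (0.0557). Its log2 fold change was 2.43 without vehicle mouse 7. The mean log2 value of the list was 6.71 and 6.99 in the vehicle females, mice 5 and 6, and 5.89 and 6.06 in the vehicle males, mice 7 and 8. Without vehicle mouse 6, 36 of the genes rose and 2 fell.

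Immediate-early genes, which also respond to cell dissociation, and glucocorticoid-responsive genes were examined as signs of handling and stress. Of 30 immediate-early and dissociation genes 20 rose, 2 fell and 8 were not called, and 21 rose and 2 fell adjusted over the list alone (median log2 1.49, camera adjusted p = 2.61e-06, and adjusted p = 0.268 with an estimated correlation). Fos, a subunit of the AP-1 transcription factor, rose from 1.84 ± 1.39 to 208 ± 144. The 2 that fell were Rgs1 and Rgs2, regulators of G-protein signalling, at -2.11 and -2.13, named after their values were seen. Of 17 glucocorticoid-responsive genes 5 rose, 7 fell and 5 were not called, also adjusted over the list alone. Their median log2 fold change was -0.67 and their mean 0.51, and camera's direction was down (adjusted p = 0.678). The members with the largest rises also respond to inflammatory signals: Lcn2, which binds bacterial siderophores, was at 6.33 (7.26 without vehicle mouse 6) and Cdkn1a, a cell cycle inhibitor, at 3.87.

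Genes for making ribosomes rose together. Of 31 tested genes of ribosome biogenesis and MYC targets, 31 rose, also adjusted over the list alone (median log2 1.25, camera adjusted p = 1.03e-14, and adjusted p = 0.143 with an estimated correlation). Rrp12, a ribosomal RNA processing factor, rose by 2.07, and Gnl3, a nucleolar GTPase, by 1.80. Among 41 ribosomal protein genes 34 rose, 0 fell and 7 were not called by limma, with 0 lower at an unadjusted p under 0.05 and 0 lower by edgeR or DESeq2, and 36 rose adjusted over the list alone (median 0.50, camera adjusted p = 1.06e-07, and adjusted p = 0.42 with an estimated correlation). Rps2 and Rps19 rose by 1.20 and 1.14, and counts of such genes are uncertain because of near-identical pseudogenes. Of 12 mitochondrially encoded genes limma called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 called by edgeR or DESeq2 (median -0.12, camera adjusted p = 0.415). The value of mt-Co1, a respiratory chain subunit, was -0.06 (adjusted p = 0.66), and in males alone it was called at -0.21 (adjusted p = 0.0132).

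Metabolic genes changed in both directions. Of 24 genes of cholesterol biosynthesis and uptake 13 rose, 1 fell and 10 were not called, and 14 rose and 1 fell adjusted over the list alone (median log2 0.91, camera adjusted p = 0.00167, and adjusted p = 0.143 with an estimated correlation). Hsd17b7, a sterol reductase, rose by 2.20. The member that fell was Dhcr7, the last enzyme of cholesterol synthesis, at -0.82, where 3 of 4 IL-33 mice lay below all vehicle mice. Dhcr7 was named after its value was seen. Its adjusted p ran from 1.79e-05 to 0.174 over all alternatives, so the call was not kept in all of them. Of 21 genes of cholesterol efflux and lipid handling 8 rose, 7 fell and 6 were not called, also adjusted over the list alone. Their median was -0.03 and their mean 0.59, and camera's direction was up (adjusted p = 0.968). Lpl, lipoprotein lipase, rose by 3.87, and Pnpla2, which breaks down stored fat, was at -1.76. Of 25 genes of glycolysis and glucose uptake 13 rose, 4 fell and 8 were not called, also adjusted over the list alone (median 0.36, camera adjusted p = 0.119). Pfkfb3, an activator of glycolysis, and Slc2a1, a glucose transporter, rose by 2.40 and 1.48, and Pdk1, which restrains pyruvate oxidation, was at -2.21. Of 22 cell cycle genes 6 rose, 5 fell and 11 were not called, also adjusted over the list alone (median 0.21, camera adjusted p = 0.65). Top2a and Mki67 rose by 3.12 and 2.85 but stayed at 28.6 ± 7.50 and 70.0 ± 20.8, and Cenpf was at -2.36. Without vehicle mouse 6, 9 of the cell cycle genes rose and 4 fell.

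**Figure D2:**
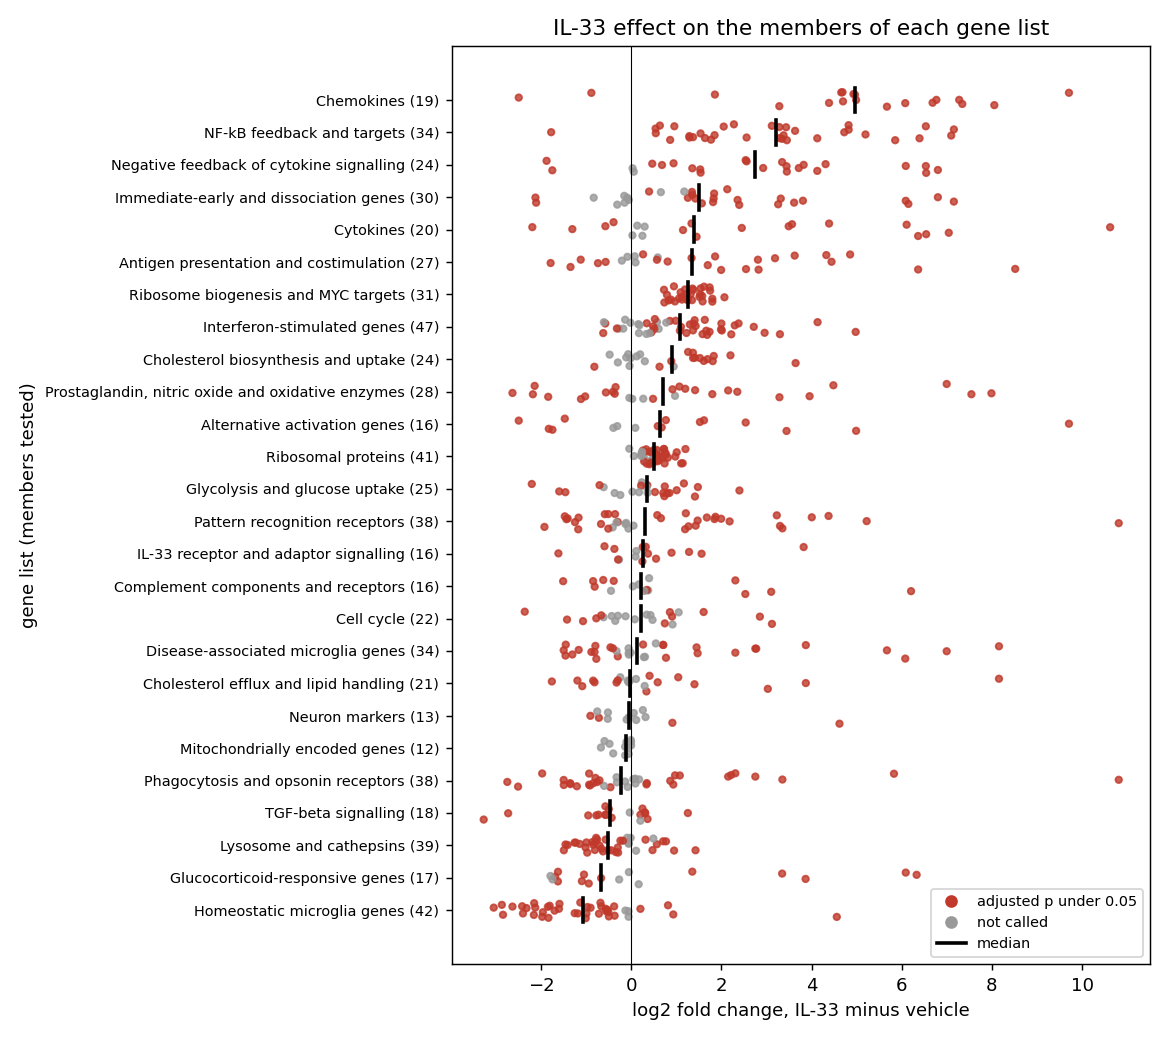
Log2 fold change (IL-33 minus vehicle) of each tested member of the gene lists with at least 12 tested members, with called genes in red, others in grey and medians as black bars. Chemokines had the highest median (4.96) and homeostatic microglia genes the lowest (-1.07).

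Markers of other cell types that a sort could hold were mostly few and low, and went both ways. Adjusted over the list alone, counts were as given unless stated. Of 13 tested neuron markers 2 rose, 2 fell and 9 were not called (2 rose and 1 fell adjusted over the list alone), with a median of -0.06, a mean of 0.21 and camera's direction up (adjusted p = 0.968). The rise was led by Eno2, a glycolytic enzyme also made outside neurons, at 4.62. Of 9 astrocyte markers 1 rose, 2 fell and 6 were not called, with a median of 0.03, a mean of -0.26 and camera's direction down (adjusted p = 0.968). S1pr1, a sphingosine phosphate receptor on this list, was at -2.46. Among 8 oligodendrocyte lineage markers 3 rose, 2 fell and 3 were not called (camera adjusted p = 0.968), and Trf, transferrin, was at -1.63. Of 5 endothelial and mural markers 1 rose, 3 fell and 1 was not called (camera adjusted p = 0.415), with Pdgfrb, a receptor of mural cells, at 2.54 and Kdr, a receptor of endothelial cells, at -1.85. Of 6 border-associated macrophage markers 1 rose, 4 fell and 1 was not called, and 2 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.224).

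Markers of blood cells were examined in the same way. Of 9 tested monocyte markers 4 rose, 2 fell and 3 were not called, and 4 rose and 3 fell adjusted over the list alone. Their median was -0.21 and their mean 1.51, and camera's direction was up (adjusted p = 0.322). Those that rose included Cd44, a hyaluronan receptor, by 7.41, Itga4, an integrin subunit, by 4.13, and Vcan, a proteoglycan, by 3.26. Ccr2, the chemokine receptor of monocytes, chosen after its values were seen, fell from 63.4 ± 15.8 to 17.2 ± 5.35. Ly6c2, a surface marker of monocytes also chosen afterwards, had 1 read in the IL-33 group and 0 in the vehicle group. Of 18 neutrophil markers 2 were tested, and 1 rose (Lcn2) and 1 fell, Csf3r, by 0.34 on the log2 scale (adjusted p = 0.0217), with 1 of 4 IL-33 mice below all vehicle mice. The call of Csf3r was lost when IL-33 mouse 3 or 4 or vehicle mouse 5, 7 or 8 was left out (adjusted p = 0.0554 to 0.0756). S100a8, an abundant neutrophil gene named afterwards, had 0 reads in both groups, which puts a floor of 0.0938 RPM (3 counts) under what could be seen with IL-33. Of 4 lymphocyte markers 2 rose and 2 fell, with Cd79b, a subunit of the B-cell receptor, at 1.28 and Klrd1, a natural killer cell receptor, at -4.01. Of 5 markers of innate lymphoid and mast cells 1 rose, 3 fell and 1 was not called (camera adjusted p = 0.163). Hdc, the enzyme that makes histamine, rose to 47.4 ± 9.62 with 1 read in all vehicle mice, and Il7r, the interleukin-7 receptor, was at -3.70. The 1 red cell marker tested, Alas2, was not called (log2 -0.59, adjusted p = 0.0823), but was called without IL-33 mouse 3 (-0.86, adjusted p = 0.0137) or vehicle mouse 8 (-0.76, adjusted p = 0.0438). For the neutrophil, lymphocyte, innate lymphoid and mast cell, and red cell lists the counts were the same adjusted over the list alone.

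Of the 32 lists tested, camera called 12 with the preset correlation, where 13 had an unadjusted p under 0.05, and 0 with an estimated correlation, where 8 had one. The preset correlation also called up to 10 lists in splits that divide the IL-33 mice evenly, so its adjusted p-values can overstate the evidence. Fry, which asks only whether members move one way on balance, called 27. In the authors' deposited table, 3519 genes were higher and 3510 lower with IL-33. Of its 7029 genes 6760 were tested here, all 6760 with the same direction, and 6758 were called, while 269 were not tested because of low counts. A further 1958 genes called here were not in the authors' deposited table, which stops at an adjusted p of 0.00996.

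The second comparison, between female and male mice, checked the labels and measured the size of a known factor. Genes on the Y chromosome were read in males and nearly unread in females. Ddx3y, an RNA helicase gene of the Y chromosome, was 674 ± 83.7 in males and 0.483 ± 0.567 in females (log2 8.90, adjusted p = 1.71e-12), and Xist, the RNA that silences an X chromosome, was 31397 ± 3278 in females and 36.8 ± 19.4 in males (log2 -9.82, adjusted p = 0.000373). In all, 9 genes were called by limma, 6 higher in males, all on the Y chromosome, and 3 higher in females, all on the X chromosome. Of autosomal genes limma called 0, with 717 at an unadjusted p under 0.05, while edgeR called 1 and DESeq2 11. The others higher in males were Eif2s3y, Kdm5d, Uty, Gm18665 and Gm4017. Eif2s3x and Kdm6a, which escape X inactivation, were higher in females by small margins (log2 -0.71 and -0.67, adjusted p = 0.00284 for both), and neither was called by eBayes without trend (adjusted p = 0.332 and 0.571). Without vehicle mouse 6, 14 genes were called. Of the 9 tested sex chromosome genes on the fixed list, 3 were called higher and 2 lower with IL-33 and 4 were not called, also adjusted over the list alone. Calls of Y-linked genes can rest in part on few reads in females. Kdm5d (log2 0.92 for IL-33, limma adjusted p = 0.0134) was 3.04 and 0.992 in IL-33 females and 0 in both vehicle females. In males it was 913 and 978 with IL-33 and 748 and 758 with vehicle.

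The third comparison asked whether IL-33 acted differently in females and males. St6gal1, a sialyltransferase (chromosome 16, 23224740 to 23360350), fell more in males. Its normalized counts with vehicle were 525 and 466 in females and 745 and 853 in males, and with IL-33 93.3 and 93.3 in females and 34.8 and 31.2 in males. The log2 effect was -2.39 in females and -4.56 in males, a difference of -2.16 ± 0.25 (SE, adjusted p = 0.00206, n = 2 per sex and treatment). It was the 1 gene called by limma, while 1255 genes had an unadjusted p under 0.05 and 18 an adjusted p under 0.1. The call was lost without vehicle mouse 7 (adjusted p = 0.0558) or vehicle mouse 8 (0.0530) and by eBayes without trend (0.173). The count of called genes rested on single mice: it was 371 without vehicle mouse 5, 9 without vehicle mouse 6, 3 without IL-33 mouse 2, 2 without vehicle mouse 8 and 0 without vehicle mouse 7, and edgeR and DESeq2 called 4 and 30.

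**Figure D3:**
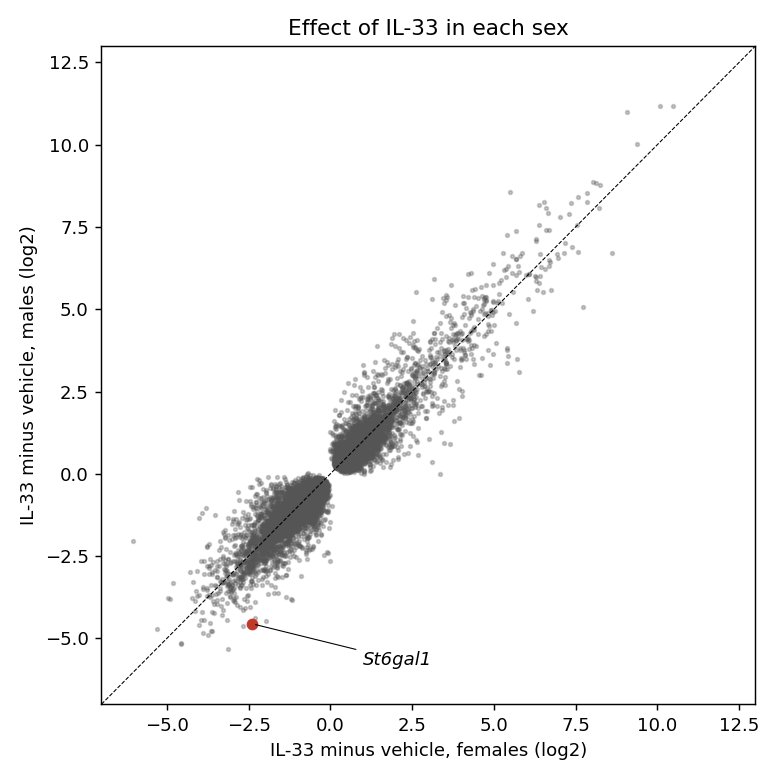
Log2 effect of IL-33 in females (horizontal) and males (vertical) for the 8716 genes called for IL-33, with the dashed line marking equal effects. St6gal1 (red) lay at -2.39 in females and -4.56 in males.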

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

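Except for the planned test behind the St6gal1 difference, the tests in this part were chosen only after the results were seen. Single mice were examined with Dixon's test within groups of 4, on log2 values of genes and on unlogged depth and read shares of the libraries. Chance passes it in about 1 in 20 groups of continuous values. That rate does not hold where the other 3 mice are at 0, as for Ptges, since any read then passes. Some genes tested, CT010467.1 among them, were named after their values were seen. Of 270 groups tested, 16 (5.93%) held a mouse far from the other 3, and 5 of those mice were vehicle mouse 6.

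Among genes with higher counts, Tlr2 was highest in IL-33 mouse 1 (16795), Tnfsf9 was lowest in IL-33 mouse 4 (504), and Vcan was lowest in the same mouse (137). Rgs1 was highest in IL-33 mouse 1 (99.4), Adamts16 was lowest in vehicle mouse 5 (220), and Alas2 was lowest in vehicle mouse 8 (33.0). Mki67 was highest in vehicle mouse 8 (24.0), and Cdkn1a was highest in vehicle mouse 6 (234). The ribosomal RNA gene CT010467.1 was lowest in vehicle mouse 6 (26319). Other such values came from few reads: Marco at 0 in vehicle mouse 7, Fpr1 and Hdc at 1.09 in vehicle mouse 6, Ptges at 0.841 in vehicle mouse 5, Adora2a at 0.915 in vehicle mouse 7, Lcn2 at 12 in vehicle mouse 6 and Smad6 at 4.71 in IL-33 mouse 3. For St6gal1 the effect of IL-33 differed between males and females by -2.16 on the log2 scale (limma adjusted p = 0.00206).

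Tested genes with a range over 1 log2 unit in vehicle mice numbered 2816. Vehicle mouse 6 stood apart as the highest in 28 of them, and 21 of the 28 rose with IL-33. Each other vehicle mouse was the highest in 8 to 11, of which 1 to 6 rose. Mouse 6 was the lowest in 50, against 21 to 31 for the others. No chance level was set for these counts, and genes are not independent replicates. Reads carried over from IL-33 libraries would add 1 share of the IL-33 level to every gene, and the 21 genes need shares of 0.843% or more. Of 55 other genes raised at least 64-fold, 7 allow less than that even with all their reads in mouse 6 taken as carried over (upper 95% Poisson limit, 0.18% for Marco), which argues against carry-over, while the median share over all 57 such genes explains a median of 6.43% of the excess in the 21 genes, a low value in part because these were picked for their excess. An exchanged label is argued against by its position over the called genes, 0.0991 of the way from the other vehicle mice to the IL-33 mice. No biological explanation was tested, since the labels name none for this mouse, and a response to the injection or to handling in this mouse stays open.

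Genes under a mean of 50 in vehicle mice that rose at least 64-fold (50 genes) could come from other cells that entered the sort, whose gate markers are not given. Of the monocyte list 4 of 18 genes lay above all vehicle mice and at 10 or more in all IL-33 mice (Cd44, the most abundant at a mean of 2678, Itga4, Vcan and Ms4a4c), while Ly6c2 had 1 read with IL-33 and Ccr2 fell, and of the neutrophil list 1 of 18 did (Lcn2), with S100a8 at 0 reads, which argues against both cells. Against dendritic cells stands a sum of the class II genes H2-Aa, H2-Ab1 and H2-Eb1 of at most 3.74% of Ccr7 in any IL-33 mouse, but 8 of 18 genes of the added dendritic cell list rose in the same way, with Fscn1 the most abundant (7794), so these cells are less firmly argued against. Vehicle microglia already held 9, 1 and 10 genes of the 3 lists at a mean of 10 or more (Csf3r at 5573), and 2, 2 and 8 of the genes stand on another list. A rise within microglia is a hypothesis made on the same data, and a few cells of another type stay open.

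Interferon-stimulated genes responded more in males than in females, with a median difference (male minus female effect) of 0.70 log2 units and 41 of 47 genes above 0. Camera's adjusted p was 6.31e-18, and 0.18 with an estimated correlation. But in the same camera test 9 other lists of 32 had a difference called below 0. Ribosomal proteins (adjusted p = 5.16e-09), lysosome (5.31e-09) and mitochondrially encoded genes (9.15e-06, 0 of 12 above 0) were among them. For ribosomal proteins, which rose with IL-33, this is a smaller rise in males. For lysosome genes, most of which fell, it is a larger fall. With an estimated correlation camera called 0 lists, with 3 at an unadjusted p under 0.05. Without vehicle mouse 6 the median was 0.64, and without vehicle mouse 5 it was 0.90, so mouse 6 alone is argued against as the source. The IL-33 mice had list means of 7.49 to 7.66, and the difference lay in the vehicle mice, at 6.71 and 6.99 in females and 5.89 and 6.06 in males. Of the 3 ways to split the 4 vehicle mice into pairs, 1, the split by sex, gave a difference as large (0.87, against 0.22 and 0.06). Sex of the mice and chance between these 4 mice cannot be told apart, since 3 splits are too few.

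The numbers of calls were set against other splits of the 8 mice into groups of 4. Of 35 splits 34 could be fitted, the real split included in these and in each count below. For IL-33, 1 of 34, the real split, gave as many as 8716 genes, and the highest other gave 0. In the other splits the IL-33 effect has no term of its own and counts as noise, which holds their calls down. A share of 1 in 34 is also the smallest these splits can give, so chance is argued against but not excluded. For sex, 2 of 34 gave as many as the real 9 genes, the highest other also giving 9, so the count alone does not exclude chance. The genes do: the 6 higher in males lay on the Y chromosome, which held 8 of the tested genes, and the 3 higher in females on the X chromosome, while of the 9 genes of that other split 0 lay on either. For the lists, 3 of 34 gave as many as the real 12, the highest other also giving 12. This comparison cannot decide on chance, because 16 of the other splits keep 3 of the 4 IL-33 mice together. Those 16 carry part of the IL-33 effect (8 to 12 lists). The 17 others divide the IL-33 mice evenly and gave 0 to 10 lists, and these 18 splits with the real one are too few for a share under 0.05. Camera with the preset correlation thus called lists where IL-33 and vehicle are not contrasted, so its adjusted p-values can overstate the evidence. For sex, it called 13 lists in the real split, with its 9 genes, and 1 to 15 in the other splits.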

How the results depend on the processing

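All alternatives below were planned, except list tests within each sex. Of 2874 values of 139 named genes under alternatives, 2819 kept their direction and their side of the threshold, 41 lost and 4 gained the call, and 10 reversed. Most named genes were picked for large changes in the main fit, which favours such stability. Over all genes, 7915 to 8225 of the 8716 calls were kept with a mouse left out, 6155 in females only and 7075 in males only. The genes changed by IL-33 numbered 6336 (females only) to 9385 (no filter), and 3861 (1694 higher, 2167 lower) with a log2 fold change of at least 1, a stricter criterion. The overlap with the authors' deposited table lay between 6720 and 6760. Sex differences numbered 18 with no filter, 23 with DESeq2 and 9 to 14 with a mouse left out (14 without vehicle mouse 6). Effects differing by sex numbered 29 with no filter, 6 with array weights, 0 by eBayes without trend (1154 at an unadjusted p under 0.05), 4 with edgeR, 30 with DESeq2 and 0 to 371 with a mouse left out (0 without vehicle mouse 7, 371 without vehicle mouse 5), where the lone mouse of its sex and treatment is assumed to vary like the others. Camera called 12 lists under each mouse left out, 0 with an estimated correlation, and fry 27.

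Cx3cr1, not called, changed direction to 0.057 in females only. mt-Co1, not called, did so to 0.088 in females only and to 0.0066 without vehicle mouse 6, and lay between -0.18 and 0.0066 with a mouse left out. CT010467.1 was at -0.29 with array weights, -0.24 with edgeR and with DESeq2, -0.75 in males only, and between -0.66 (without vehicle mouse 6) and 0.38 (without vehicle mouse 5) with a mouse left out. For 6 uncalled lists the direction changed in some settings, and the adjusted p was as follows, with ranges over all 8 fits with a mouse left out, of which some changed direction. Cholesterol efflux: 0.675 (filter of 50), 0.858 (quantile), 0.616 (males only), 0.820 to 0.970. Glucocorticoid genes: 0.966 (fry), 0.959 (females only). In females only, mitochondrial genes were at 0.721 and neuron markers at 0.801 (0.811 to 0.964). Astrocyte markers: 0.905 (no filter), 0.965 (quantile), 0.989 (males only), 0.843 to 0.997. Oligodendrocyte markers: 0.196 (fry), 0.697 (filter of 50), 0.985 (no sex term), 0.718 (males only), 0.849 to 0.997. The cause was not tested. Irf8 was not called with edgeR (0.0561) or DESeq2 (0.0739).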

Other observations

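The tests in this part were chosen after the values were seen, except the planned limma test of single genes and the test of small nucleolar RNAs against their host genes, which was set before its result was seen. Genes named here were chosen after their values were seen. No list of transcription factors was tested, and the values of single factors differed in size. Sall1, a factor of microglial identity, fell from 9512 ± 1060 to 2920 ± 298 (SD, n = 4 per group), and Mef2a from 12448 ± 682 to 5684 ± 277. Cebpa, a myeloid factor, was at a log2 fold change of -2.23, Etv1 at -3.40 and Ebf3 at -3.64. Irf8, a factor of myeloid cells, differed least, at -0.20 (limma adjusted p = 0.0473), with 3 of 4 IL-33 mice below all vehicle mice, a call that was lost without IL-33 mouse 2 or 4 or vehicle mouse 5, 6 or 7. Csf1r, the receptor that microglia need to survive, was at -0.68, a call that was lost after quantile normalization (-0.43, adjusted p = 0.326, with adjusted p from 1.28e-13 to 0.326 over all alternatives).

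Some genes outside the fixed lists, picked for their rise from low levels and not tested as a group, follow. Cd69, an early activation marker that holds cells in tissue, rose from 3.60 ± 3.79 to 1183 ± 189 (log2 8.44). Gpr132, a receptor for lactate and oxidized lipids, rose to 326 ± 81.1 from 1.53 ± 2.40. Adora2a, an adenosine receptor, rose to 145 ± 28.4, with 1 read in all vehicle mice together. Ikbke, a kinase of the interferon and NF-kB pathways, and Ehd1, an endosomal recycling protein, rose by 7.78 and 7.30, and Ikbke was at 7.08 without vehicle mouse 5 and 8.66 without vehicle mouse 6. The adjusted p of Ikbke ran from 2.50e-17 to 0.101 over all alternatives, so its call was not kept in all of them.

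Some classes of genes differed in direction. Of called protein-coding genes 52.3% were higher with IL-33, against 32.4% of long intergenic RNAs (84 higher, 175 lower, Fisher's exact test, adjusted p = 2.42e-09 over 10 classes). The share was 33.3% for processed transcripts (adjusted p = 0.000174), 41.9% for antisense RNAs (0.00101) and 43.7% for loci annotated as awaiting experiment (0.000845), and 35.7% for sense intronic RNAs (0.0253). Of called small nucleolar RNAs 85.3% were higher (29 higher, 5 lower, adjusted p = 0.000299). The shares of processed pseudogenes (51.9%), microRNAs (52.2%), small nuclear RNAs (46.2%) and transcribed processed pseudogenes (44.4%) were not called different from that of protein-coding genes. Genes are not independent replicates, and antisense counts are uncertain without a stated strand setting.

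Small nucleolar RNAs are mostly cut from introns of host genes, and a hypothesis was that they rise where their hosts do. Of 72 tested, 49 lay in a tested host, and across 48 host genes the log2 fold changes correlated (Spearman's rho = 0.564, Pearson's r = 0.795, permutation p = 0.0001, the smallest that 10000 permutations can give, for rho). The correlation is across genes, which are not independent replicates. Of the hosts 32 were called higher and 8 lower. The result is consistent with host transcription as a candidate source, but intronic reads of the host counted as the small RNA stay open.

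In the deposited normalized counts, the symbols beside the gene identifiers did not match them in a stretch of chromosome 8. Between 119910360 and 124331795, 0 of 61 identifiers with a mean normalized count of 10 or more carried the GENCODE M21 symbol, and 60 carried the symbol of another gene. Irf8 lies in this stretch, and its identifier carries the symbol 4930569F06Rik, so a search for Irf8 by symbol finds no entry in the table used here. Over all chromosomes, 67 identifiers at such a count carried the symbol of another gene. The authors' deposited table of their comparison holds 30 of these, and 25 carry the GENCODE M21 symbol there.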
